A study of Mus musculus with 8 samples.

How the data were processed

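RNA from 8 mouse tissue samples was hybridised to Affymetrix 1-colour arrays. Lungs of 3 single transgenic control embryos and 3 embryos carrying both transgenes (MIA bitransgenic) were taken at embryonic day 18.5 (E18.5) in the FVB/N strain and measured on 1 array type. A lung and a trachea sample from E11.5 were measured on an older array type, with 1 array each. The labels describe the E18.5 groups as an SP-C/MIA control and overexpressor, and do not say which of the transgenes the controls carried.

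Per the labels, the deposited values were made with MAS5, with no version stated. The unit of both deposited tables is intensity, a linear signal for each probe set. The values themselves show that each of the 8 arrays had a 2% trimmed mean of 1500, with medians that differed, and that no logarithm had been taken. The tables as used here held 1 signal per probe set and array, without detection calls.

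Control probe sets were left out, 64 on the E18.5 array and 66 on the E11.5 array. Probe sets were named from the array annotation. On the E18.5 array 34945 of 45037 probe sets had 1 gene symbol, 932 had several and 9160 had none, which gave 18193 genes. On the E11.5 array 10833 of 12422 had 1 symbol, which gave 8251 genes. Values were analysed as log2 of the signal plus a pseudocount, set at the 20th percentile of the table (86 for E18.5 and 84 for E11.5). A gene was represented by its probe set with the highest mean log2 value. Genes were kept when that mean was at or above the 40th percentile of all probe sets, which left 12625 genes at E18.5 and 5699 at E11.5. Changes close to the pseudocount are compressed by it, so the fold of a gene with a signal near 86 or 84 in either sample depends on that choice. The number of arrays limits the precision.

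The E18.5 groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend. P-values were two-sided and adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Exact permutation of 3 arrays against 3 gives 10 splits and no p under 0.1, so the model that pools the variance across genes was used. No covariate was fitted, and no number or label pairs an array of 1 group with an array of the other. The sample titles number all controls before all bitransgenic arrays, so an effect of that order, if any, cannot be told from the group. Gene lists of cell types and pathways were compared by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members, with camera at an estimated correlation and fry beside it. The E11.5 arrays have no replicates, so no test was made. A gene was counted as apart when its ratio exceeded 2-fold and its higher signal was above the median of the table. A list was counted as apart when its median log2 ratio lay outside the central 95% of 10000 random lists of the same size, matched on expression. The 100 most lung-biased and 100 most trachea-biased E11.5 genes, among genes on both array types whose higher E11.5 signal was above the median and without the E11.5 filter on the mean, were carried to the E18.5 arrays and compared by camera.

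The comparisons and their tests, the gene lists of the report and the rule for naming genes were set before the data were examined. The closing section names the tests and alternatives that were chosen later. The rule named Mia, the 12 largest rises and 12 largest falls among genes past the threshold with groups that did not overlap, up to 4 members of each described list with the smallest p (at E11.5 the largest ratio), a fixed set of lung marker genes, and at E11.5 the 12 largest ratios each way plus a fixed set of developmental genes. Genes with clone names were counted but not named. The lists written later, of pan-epithelial genes, core endothelial genes and pharyngeal and neural crest genes, are used in the closing section alone.

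The E18.5 test was tested on simulated data with 200 changed genes among 12625 in each of 10 runs. It recovered 27.6% of genes changed by 1.5-fold, 81.9% at 2-fold and 99.5% at 4-fold, with 5.6% false among the calls. Camera found the shifted list in 10 of 10 runs and called an unshifted list in 1 of 10. The noise was drawn independently for each gene and the lists were random. The simulation therefore does not cover correlated genes, and the estimated correlation within the alveolar type II list was 0.261.

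Alternatives covered median centring and quantile normalization, pseudocounts of 0 and 4 times the size, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, probe sets in place of genes, other variance models, array weights, other thresholds and set sizes, and each replicate left out in turn. A sex covariate, the Actb 3' to 5' ratio as a covariate and the loss of both arrays with the lowest correlation to the others were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python.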

Results

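The series measured gene expression in embryonic mouse lung on 8 arrays. It asked how misexpression of MIA, a secreted protein first described in melanoma and cartilage, alters the E18.5 lung, and which genes differ between lung and trachea at E11.5. The E18.5 groups held 3 single transgenic control lungs and 3 MIA bitransgenic lungs. Their median signals ran from 415 to 464, with equal trimmed means of 1500. The E11.5 lung and trachea arrays had medians of 541 and 545.

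The E18.5 arrays were close to one another within and between groups. Across genes, which are not independent replicates, the correlation of log2 values was between 0.967 and 0.981 within groups and between 0.962 and 0.979 between groups. Control 3 and bitransgenic 3 had the lowest mean correlation with the other arrays, 0.966 and 0.967. The 3' to 5' signal ratio of Gapdh was 0.921, 0.921 and 0.781 in the controls and 0.996, 0.921 and 1.08 in the bitransgenic lungs, and that of Actb was 1.5, 1.47 and 1.28 against 1.65, 1.51 and 1.61. The Actb ratio, a sign of RNA quality, was thus higher in all 3 bitransgenic arrays than in all 3 controls, and moved with the group in every E18.5 comparison below. Xist and Y-linked signals gave 1 male and 2 females in each group.

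Mia rose far above every other gene that rose in the bitransgenic lungs. Its single probe set (gene on chromosome 7, 27179741 to 27181149 on the mouse reference GRCm38) read 959 ± 194 (SD, n = 3) in the controls and 38540 ± 6207 (SD, n = 3) in the bitransgenic lungs. The log2 change was 5.21 with an SE of 0.18 (n = 3 per group, limma adjusted p = 1.07e-06). The bitransgenic arrays all lay above the controls. The control mean lay above the median signal of the arrays.

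Beyond Mia, the largest falls were those of Scd1 and Sftpa1. Scd1, the stearoyl-CoA desaturase (chromosome 19, 44394450 to 44407709), fell from 38420 ± 3048 (SD, n = 3) to 1214 ± 458 (SD, n = 3), and Sftpa1, which encodes surfactant protein A (chromosome 14, 41131788 to 41136373), fell from 41600 ± 879 (SD, n = 3) to 1845 ± 374 (SD, n = 3). Their log2 changes were -4.94 (SE 0.21, n = 3 per group, limma adjusted p = 5.58e-06) and -4.45 (SE 0.15, n = 3 per group, limma adjusted p = 1.07e-06). The largest rise after Mia was Gstm5, a glutathione S-transferase (chromosome 3, 107895854 to 107898685), from 4134 ± 694 (SD, n = 3) to 24510 ± 3728 (SD, n = 3), a log2 change of 2.55 (SE 0.16, n = 3 per group, limma adjusted p = 9.7e-05).

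Other large rises came from genes of several kinds. Rspo2, an activator of Wnt signalling, rose by 1.64 on the log2 scale and Cdh16, a cadherin best known from kidney, by 1.60. The chromatin protein gene Hmga2 rose by 1.19, the small matrix proteoglycan gene Fmod by 1.40, and Flrt3, which encodes a membrane adhesion protein, by 1.17. Vstm2b, Rtl3, Atp13a4, Fam184a and the profilin gene Pfn2 had log2 changes of 2.41, 1.74, 1.42, 1.28 and 1.23. Among the falls, Acoxl dropped from 2459 ± 813 (SD, n = 3) to a signal below the pseudocount, 60.1 ± 62 (SD, n = 3), so that its log2 change of -4.15 depends on the pseudocount. The complement component gene Hc, the lipocalin gene Lcn2 and S100g, which encodes a calcium-binding protein, had log2 changes of -3.23, -2.70 and -2.66, the last of them also dependent on the pseudocount (bitransgenic signal 96.5 ± 91.7, SD, n = 3). The paraoxonase gene Pon1 fell from 4019 ± 1118 (SD, n = 3) to 439 ± 205 (SD, n = 3). Klk13, Retnla, Bex2 and Chil1 had log2 changes of -2.65, -2.58, -2.58 and -2.27.

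**Figure D1:**
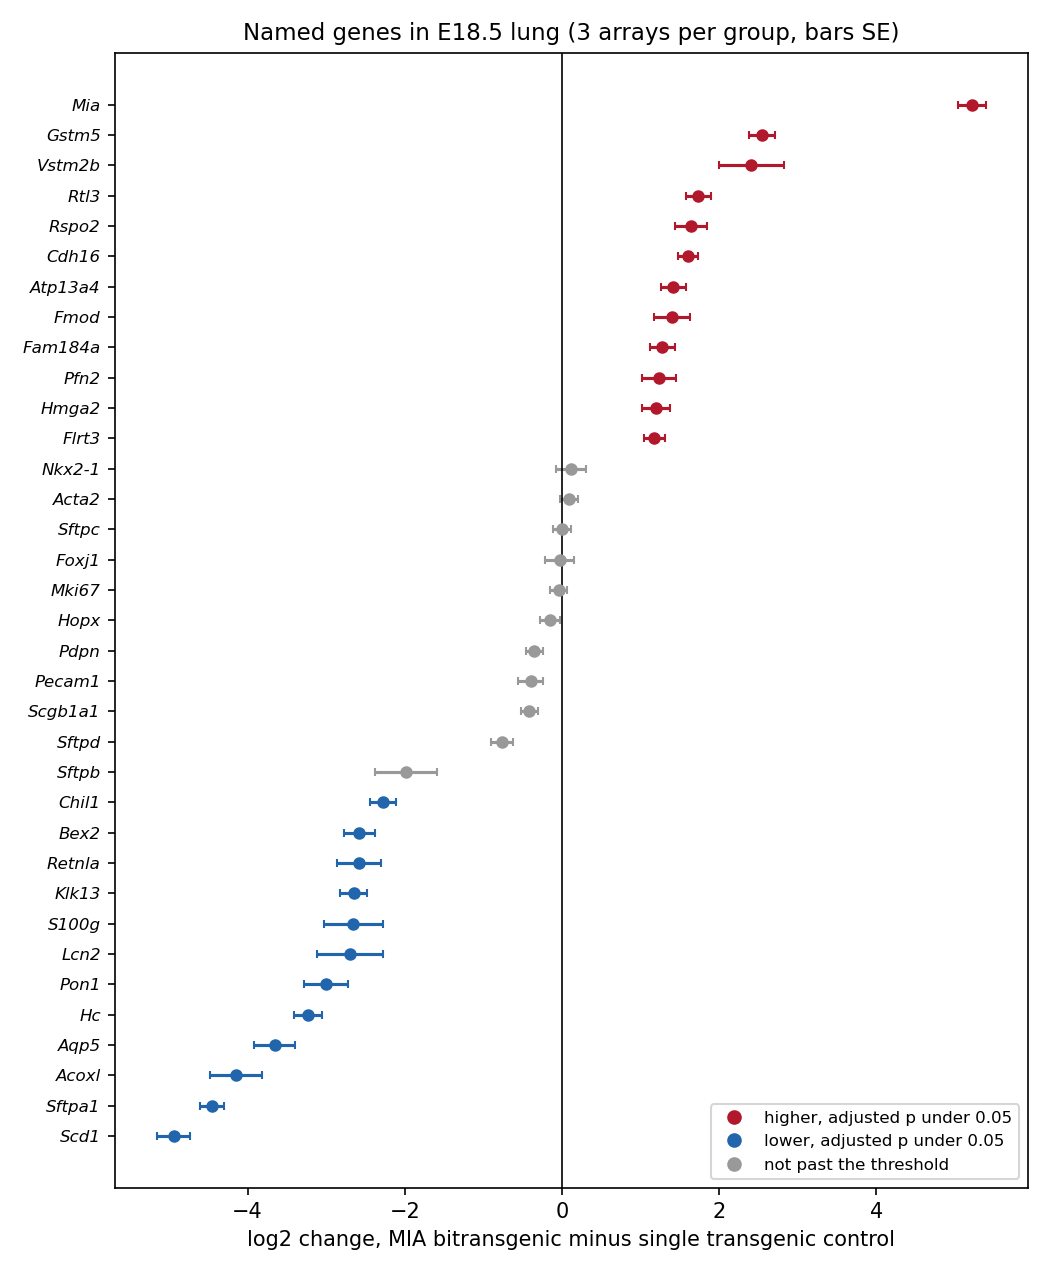
Log2 change (horizontal axis, bitransgenic minus control) of each named gene in E18.5 lung, with bars for the SE (n = 3 per group) and colour for the side of the adjusted p threshold. Mia is highest at 5.21, Scd1 is lowest at -4.94, and Sftpc lies at 0.00.

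In the limma fit 85 of 12625 genes passed the adjusted threshold, 30 higher and 55 lower in the bitransgenic lungs. Of these, 20 were higher and 44 lower by at least 2-fold, and for all 85 the groups did not overlap. Across all genes 2072 (16.4%) had groups that did not overlap, where chance gives 10%. The count fell to 22 without control 2, 40 without bitransgenic 1, 56 without bitransgenic 2 and 35 without bitransgenic 3, and was 187 without both arrays of low correlation, 1339 with array weights and 20 with the Actb 3' to 5' ratio as a covariate. Of the 23 genes with the largest rises and falls besides Mia, Aqp5 included, 15 passed in all 6 fits that left out 1 array, while Vstm2b, Fmod, Hmga2 and Pfn2 passed in 2 of them and Lcn2 and S100g in 3. With the Actb ratio as a covariate, a fit with 1 residual degree of freedom fewer, those 6 genes, Rspo2, Atp13a4, Fam184a and Flrt3 did not pass but kept their signs. The share of the log2 change that remained there was 0.542 to 0.735 for the 6 genes and 0.824 to 0.884 for the last 4.

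Genes of the alveolar type II cell, which makes surfactant, had the lowest median of the lists tested. Of 28 measured members, 15 fell, none rose and 13 did not pass, and adjusted over the list alone 21 were lower. Besides Scd1 and Sftpa1, the phospholipid acyltransferase gene Lpcat1 had a log2 change of -1.19, the phosphate transporter gene Slc34a2 of -1.68 and Abca3, the lipid transporter of lamellar bodies, of -0.97. The list's median log2 change was -1.02, and -0.95 with the Actb ratio as a covariate (camera adjusted p = 4.51e-38, and adjusted p = 0.098 with an estimated correlation). Slc34a2 and Abca3 are outside the naming rule and were chosen after their values were seen. Of 3 Abca3 probe sets past the filter, 2 were lower and 1 was higher in the bitransgenic lungs.

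None of the genes of the other surfactant proteins passed. Sftpc, whose promoter is in the labels, read 84710 ± 3667 (SD, n = 3) in controls and 85320 ± 11420 (SD, n = 3) in bitransgenic lungs, near the top of the array range, and its log2 change of 0.00 turned slightly negative under median centring and quantile normalization. Sftpb read 22790 ± 16750 (SD, n = 3) against 4835 ± 751 (SD, n = 3), with control values far apart, with all bitransgenic values below the controls (log2 change -1.99, limma adjusted p = 0.0693). It passed without control 1 (limma adjusted p = 0.025) and without control 3 (limma adjusted p = 0.0057). With the Actb ratio as a covariate the log2 change of Sftpb was -0.93 (limma adjusted p = 0.71). Sftpd also had all bitransgenic values below the controls, with a log2 change of -0.76 (limma adjusted p = 0.0511). With the Actb ratio as a covariate that change was -0.49 (limma adjusted p = 0.652). Nkx2-1, the lung lineage transcription factor, had a log2 change of 0.12 (limma adjusted p = 0.896).

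Alveolar type I genes, from the flat cells of gas exchange, also shifted down. Of 24 measured members, 4 fell, none rose and 20 did not pass, and adjusted over the list alone 15 were lower. Aqp5, a water channel, fell from 4797 ± 1714 (SD, n = 3) to 290 ± 70.4 (SD, n = 3), a log2 change of -3.65. Rtkn2, Clic5 and the sodium channel subunit gene Scnn1g had log2 changes of -1.47, -1.43 and -1.20. The common type I markers Pdpn and Hopx had log2 changes of -0.36 and -0.15 and did not pass (limma adjusted p = 0.283 and 0.784), and Hopx turned positive with the Actb ratio as a covariate. The list's median was -0.35 (camera adjusted p = 5.25e-14, and adjusted p = 0.098 with an estimated correlation).

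Lists of lipid synthesis also had medians below 0. In the fatty acid and phospholipid list 2 of 20 members fell, Scd1 and Lpcat1, none rose, and adjusted over the list alone 7 were lower, with a median of -0.36 (camera adjusted p = 1.16e-09, and adjusted p = 0.098 with an estimated correlation). Scd1, Lpcat1 and Fasn are also members of the type II list, so the 2 falls were already counted there and the lists are not independent. Gpam and Acaca, which did not pass over all genes, had log2 changes of -0.63 and -0.62. No gene of 19 in cholesterol biosynthesis passed, 1 was lower adjusted over the list alone, and the median was -0.22 (camera adjusted p = 0.000455, and adjusted p = 0.098 with an estimated correlation). Its members Insig1 and Fdps had log2 changes of -0.88 and -0.83.

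**Figure D2:**
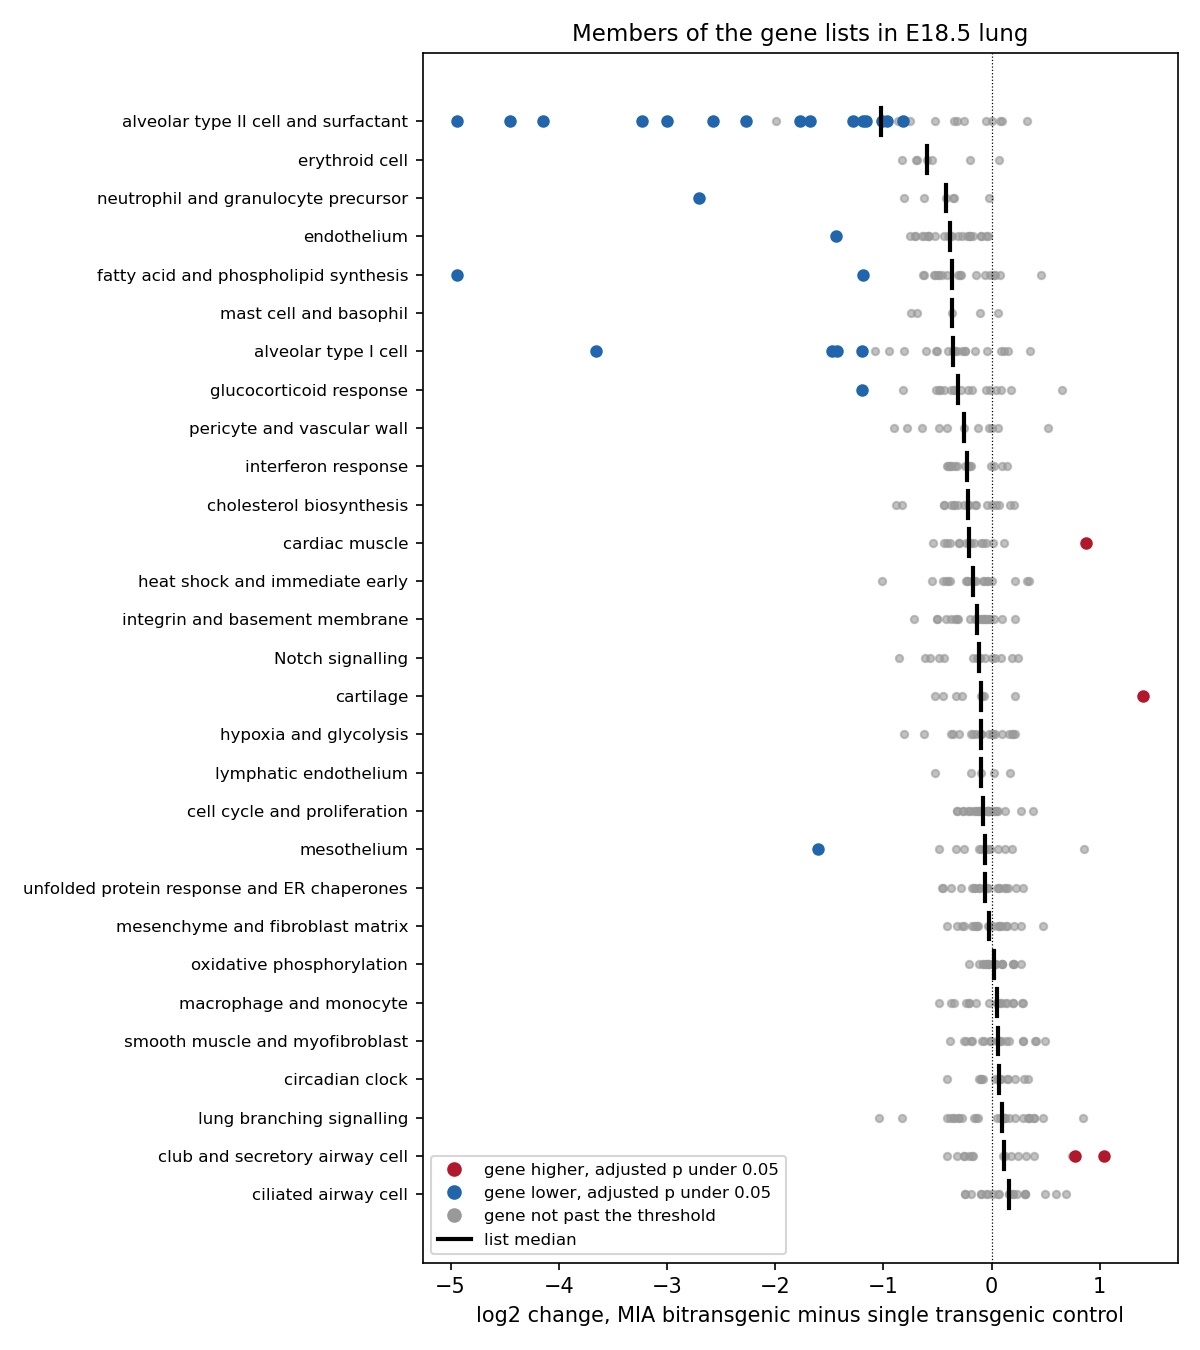
Log2 change (horizontal axis, bitransgenic minus control) of every measured member of each gene list in E18.5 lung, with colour for members past the adjusted p threshold and a bar at the list median. The alveolar type II list has the lowest median, -1.02, and the ciliated list the highest, 0.16.

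Airway lists did not move as a whole. Of 16 club cell genes 2 rose, Cckar by 1.04 and Aldh1a7 by 0.77 on the log2 scale, and none fell, while adjusted over the list alone 2 were higher and 1 lower. The club cell secretory protein gene Scgb1a1 had a log2 change of -0.42 (limma adjusted p = 0.185), and of -0.22 with the Actb ratio as a covariate (limma adjusted p = 0.832). None of 21 ciliated cell genes passed, also adjusted over the list alone, and Foxj1, the regulator of motile cilia, had a log2 change of -0.03 that changed sign without control 3, without bitransgenic 2 and with the Actb ratio as a covariate. Neither list was called by camera (adjusted p = 0.539 and 0.106).

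Few endothelial genes passed singly. All 25 measured members had negative log2 changes, 20 of them with the Actb ratio as a covariate, 1 fell (Car4, a carbonic anhydrase of lung capillaries, with a log2 change of -1.44), and adjusted over the list alone 9 were lower. Cldn5, Emcn and Ramp2 had log2 changes of -0.62, -0.71 and -0.59, and Pecam1 had -0.40 (limma adjusted p = 0.445). The list's median was -0.38, and -0.20 with the Actb ratio as a covariate (camera adjusted p = 1.24e-12, and adjusted p = 0.098 with an estimated correlation). The neutrophil and erythroid lists also had medians below 0. In the neutrophil list 1 of 7 genes fell, Lcn2, which epithelium also makes, 2 were lower adjusted over the list alone, and the median was -0.42 (camera adjusted p = 0.000101, and adjusted p = 0.098 with an estimated correlation). None of 7 erythroid genes passed, 2 were lower adjusted over the list alone, Alas2 had a log2 change of -0.83, and the median was -0.59 (camera adjusted p = 0.000956, and adjusted p = 0.098 with an estimated correlation).

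Camera called 7 further lists, all towards lower expression, of which the pericyte, mast cell, interferon, heat shock, integrin and Notch lists were not called with the Actb ratio as a covariate. The glucocorticoid response list had a median of -0.31, with Scnn1g the 1 of 18 genes that fell and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). The pericyte list had a median of -0.26 with 0 of 11 called and 2 lower adjusted over the list alone (adjusted p = 0.249 with an estimated correlation), and the mast cell list -0.36 with 0 of 5 called and 2 lower adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). In the mast cell list Kit, Hdc and Gata2 had log2 changes of -0.69, -0.74 and -0.36, while Cpa3 had -0.11 and 1 member was positive. The interferon list had a median of -0.23 with 0 of 16 called and none adjusted over the list alone (adjusted p = 0.331 with an estimated correlation). The heat shock and immediate early list had -0.17 with 0 of 20 called and 1 lower adjusted over the list alone (adjusted p = 0.098 with an estimated correlation). Integrin and basement membrane genes had a median of -0.13 with 0 of 24 called and 1 lower adjusted over the list alone (adjusted p = 0.167 with an estimated correlation), and Notch signalling genes had -0.12 with 0 of 16 called and none adjusted over the list alone (adjusted p = 0.15 with an estimated correlation).

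The remaining 13 of the 29 lists besides the airway lists showed no shift by camera. Cartilage held 1 rise among 9 genes, Fmod, and cardiac muscle 1 among 17, Myh7 by 0.87, while mesothelium held 1 fall among 13, Msln with a log2 change of -1.61, with the same counts adjusted over the list alone. No member passed among 29 proliferation genes, 20 smooth muscle genes or 21 mesenchymal matrix genes, also adjusted over the list alone. Mki67, a marker of cycling cells, had a log2 change of -0.04 that turned positive without bitransgenic 2, and Acta2, the smooth muscle actin gene, of 0.09. The macrophage list's median (0.05) and mean (-0.03) differed in sign, as did those of the branching list (0.10 and -0.01).

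Camera with the preset correlation called 14 of the 29 lists, all lower, and with an estimated correlation none after adjustment and 9 at an unadjusted p under 0.05, while fry called 7. The list calls carry less weight than the gene calls, since they were lost with an estimated correlation. Other splits of the 6 arrays gave up to 12 called lists, but each keeps part of the group difference and cannot serve as a null.

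At E11.5, Mia was among the genes with the largest lung-to-trachea ratios. Its signal was 1048 in lung and 81.4 in trachea, below the pseudocount, so that both its log2 ratio of 2.77 and its rank at the top depend on that choice. With a pseudocount 4 times as large the log2 ratio of Mia was 1.73 and that of Hoxb6 was 2.05, and with no pseudocount Mia did not pass the filter. Sftpc was also higher in lung (1503 against 257, log2 ratio 2.22), as were the Hox genes Hoxb6 (3425 against 571) and Hoxb5 (3675 against 996), the laminin gene Lama3 and the alcohol dehydrogenase gene Adh1, with log2 ratios of 2.20 and 2.22. On the trachea side the transcription factor gene Six2 had the largest ratio (233 in lung and 4345 in trachea, log2 ratio -3.81), followed among genes past the filter by the matrix gene Tnc (-3.06) and Twist1 (-2.97), a transcription factor gene of mesenchyme. Sox2, a regulator of proximal airway epithelium, read 1016 in lung and 4260 in trachea.

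**Figure D3:**
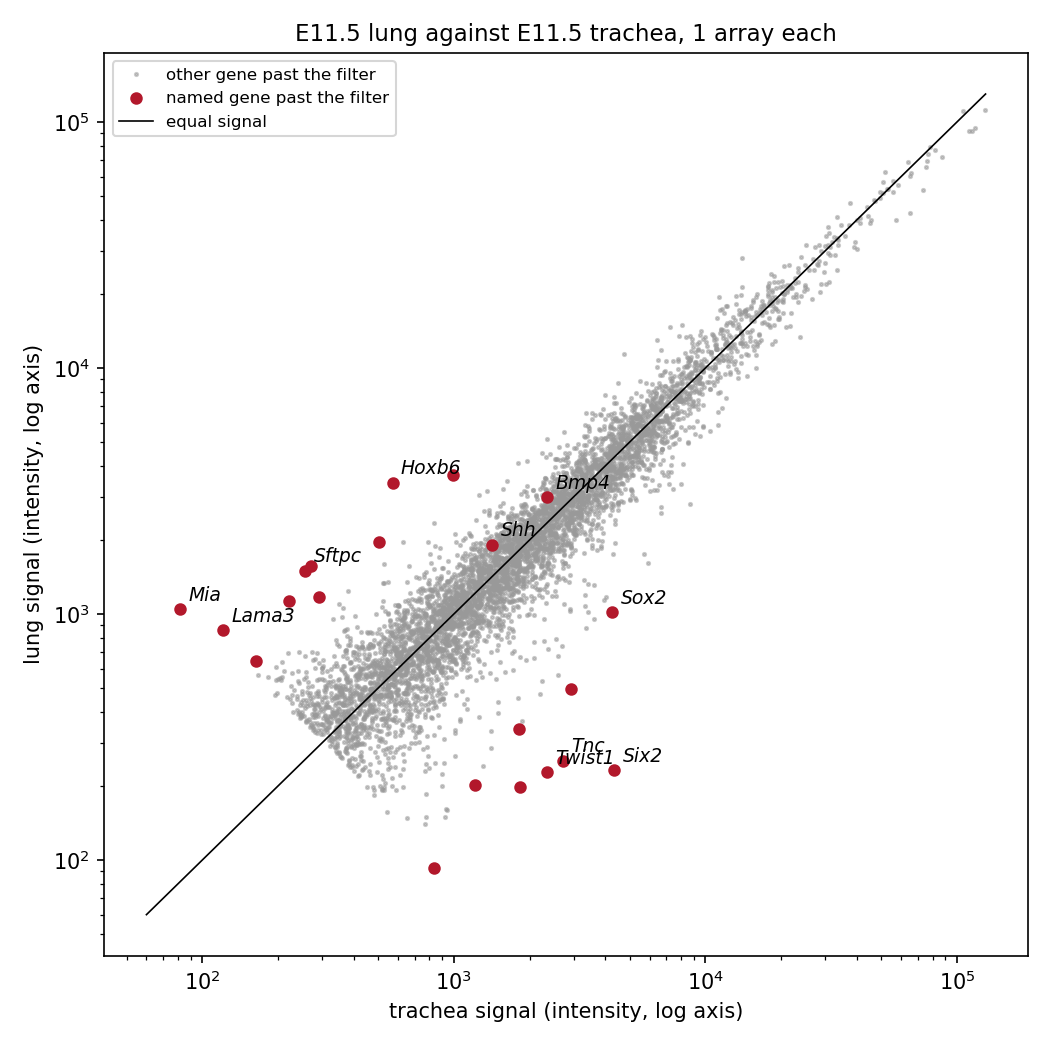
Lung signal against trachea signal (intensity, both axes logarithmic) for genes past the filter at E11.5, 1 array per tissue, with named genes in red and a line at equal signal. Mia lies at 1048 and 81.4 on the lung side, and Six2 at 233 and 4345 on the trachea side.

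Further genes with large ratios on the lung side were Ada, Cebpb, Sema3a and Aldh1a7, with log2 ratios of 1.99, 1.80, 1.75 and 1.56. On the trachea side Pea15a, Kcne1l, Ebf3, Rps6kb2 and Pkia had -2.77, -2.38, -2.38, -2.18 and -2.16, and the lung signal of Kcne1l, 92.4, was near the pseudocount. Krt19, Hcrt, Wnt5a, Dlx2, Cldn11 and Fap also ranked among the largest, but their mean signals were below the filter. Shh and Bmp4, signals of the lung bud, had small ratios of 0.41 and 0.34, and Fgf10 and Col2a1 had low signals in both samples.

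In all, 175 of 5114 genes compared (3.42%) were over 2-fold apart, 60 higher in lung and 115 higher in trachea. With 1 array per tissue there were no replicates and no test, so these ratios describe these samples alone, and the count was 95 with a pseudocount 4 times as large and 78 with a filter at the 60th percentile.

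Of 14 gene lists described at E11.5, 5 were apart towards lung and 7 towards trachea, and between 8 and 12 were apart over the settings tried. The cardiac, mesothelium, distal bud epithelium, type II and neuroendocrine lists were each no longer apart in at least 1 setting. The distal bud epithelium list was on the lung side with 16 measured members and a median log2 ratio of 0.26, at percentile 99.7 of random lists, with Wnt7b at 0.93 and Foxa1 at 0.82. Lung bud mesenchyme (median 0.35, percentile 99.7) held Foxf1 at 1.23 and Hoxa5 at 1.16, but Tcf21 at -0.96. Its members Wnt5a, at -3.70, and Fgf9, at 1.55, were below the filter and not counted in that median. The 24 cell cycle genes had a median of 0.30 (percentile 100), with Rrm2 at 0.94. The type II list had a median of 0.39 (percentile 98.9) over 7 members. Sftpc was the 1 of them over 2-fold higher in lung, Muc1 was at -0.63, and Sftpb and Sftpd were below the filter. The mesothelium list had a median of 0.35 (percentile 98.5) over 7 members, with 0 over 2-fold and Cpe at -0.64. Its members Krt18 and Krt8, at 0.64 and 0.37, are also among the pan-epithelial genes of the closing section. On the trachea side, smooth muscle genes had a median of -0.90 over 10 members, with Eln at -1.72, Tagln at -1.55 and Acta2 at -1.26, and no random list as low. Mesenchymal matrix genes had -0.47 over 19 members, with Postn at -1.84 and Dcn at -1.59, and erythroid genes -0.59 over 12, with Slc4a1 at -1.31, again with no random list as low.

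Cartilage genes had a median of -0.51 (percentile 0.27), with Col11a1 at -2.04 and Col9a3 at -1.46, but Fmod at 1.46, and the median was 0.04 with no filter. Neuroendocrine and nerve genes had -0.54 (percentile 0.35), endothelial genes -0.31 (percentile 0.27), with Vwf at -1.67, and cardiac genes -0.44 (percentile 2.24). Macrophage genes (percentile 37.4) and the Hox list (percentile 86.3) were not apart, although 4 of 14 Hox genes were over 2-fold higher in lung.

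The genes that parted lung from trachea at E11.5 did not shift in the bitransgenic lungs as sets. The sets were drawn from 6565 genes past the E18.5 filter and on both array types, without the E11.5 filter. The 100 most lung-biased, Mia among them, had a median log2 change of -0.04 at E18.5, with 3 higher and 1 lower past the threshold (camera adjusted p = 0.661, and adjusted p = 0.571 with an estimated correlation). The 100 most trachea-biased had a median of -0.00 with none past the threshold (camera adjusted p = 0.49, and adjusted p = 0.571 with an estimated correlation). The median and mean of the lung-biased set differed in sign (-0.04 and 0.01). Mia itself, with a log2 change of 5.21, was 1 of the 3 higher and accounts for the positive mean.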

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

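The tests on the share of epithelium, sex, RNA quality, the share of endothelial cells and blood were chosen after the data had been seen, while the scaling alternatives, the fits that left out 1 array and the splits were planned. When all probe sets were tested in place of genes, 13 probe sets without a single gene symbol passed the limma threshold, 10 higher and 3 lower, a signal in data that the gene comparisons do not use. The one with the largest fall read 1563 ± 124 (SD, n = 3) in controls and 350 ± 31.8 (SD, n = 3) in bitransgenic lungs, and the one with the largest rise read 196 ± 59.7 (SD, n = 3) and 822 ± 115 (SD, n = 3).

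Type II genes were lower in the bitransgenic lungs, with a median log2 change of -1.02. A lower share of epithelium would lower epithelial genes in general, but the pan-epithelial genes had a median of 0.274 (bootstrap 95% interval over genes 0.101 to 0.298), on the other side of 0. That median is from the fit without the Actb ratio, and its interval does not measure the spread between lungs. The higher value under median centring and quantile normalization was -0.997. The array medians ran only from 415 to 464, so centring could move the list little. These close medians argue against a difference in scale between the arrays. The Actb ratio, a sign of RNA quality, moved with the group, though control 1 at 1.5 and bitransgenic 2 at 1.51 were close. The Gapdh ratio did not separate the groups, with 0.921 in control 1, control 2 and bitransgenic 2. With the Actb 3' to 5' ratio as a covariate the median was -0.951. Its bootstrap 95% interval over genes was -1.36 to -0.513, just below the -0.509 set as the bound. That interval leaves out the spread between arrays, and the ratio did not overlap between the groups. The median stayed near -1.02, but the fit cannot decide how much RNA quality contributed. Of the explanations examined, RNA quality stays open. The group itself does too, since the labels do not say which transgene the controls carried and MIA cannot be separated from the presence of both. The pan-epithelial genes do not test the share of type II cells within the epithelium, and explanations that were not examined also stay open.

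Endothelial genes were lower with a median of -0.382. A single array is argued against, since the median lay between -0.427 and -0.361 in the fits that left out 1 array, with a highest camera adjusted p of 1.07e-10. That call was lost with an estimated correlation on all arrays (adjusted p = 0.098), so the p carries little weight. Camera also called this list in 6 of the other splits, but these keep part of the group difference and cannot serve as a null. With the Actb ratio as a covariate the median was -0.201 (interval -0.301 to -0.0853), so RNA quality stays open for part of the pattern. A lower share of endothelial cells stays open too, since the 17 core genes (median -0.382, interval -0.59 to -0.228) are all members of the list and cannot test it.

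Neutrophil and erythroid genes were lower, and the erythroid median minus the neutrophil median was -0.173. Less blood in the bitransgenic tissue stays open, since 2 of 7 erythroid genes had all 3 bitransgenic values below all 3 controls, where 7.56% of all genes did and chance gives 5%, too few genes to decide. No erythroid gene passed over all genes.

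With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 85 genes and the highest of the others 1, so 1 of the 10 splits reached the real count. For gene lists the real split called 14 and the highest other 12. Each other split has both groups on both sides, so it keeps part of the group difference and adds the rest to the spread. Its counts and p-values therefore cannot serve as a null for genes or for lists. The type II list had a camera p of 1.56e-39 in the real split and 4.17e-08 at the smallest in the others, and was called in 7 of those. The pericyte, mast cell and interferon lists had a smaller p in some other split than in the real 1. The lung-biased E11.5 genes had a p of 0.661 against 0.228 at the smallest in another split, with 6 of 10 splits as small, the real one included, and the trachea-biased genes 0.245 against 0.0278, with 7 of 10 as small.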

How the results depend on the processing

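The sex covariate, the Actb 3' to 5' ratio covariate and the 2 against 2 comparison were chosen after seeing the data. The count of changed genes, 85, was 1339 with array weights, where the weight of control 2 was 6.28 and the estimation did not converge fully, 165 at adjusted p under 0.10, a wider threshold by construction, 187 in the 2 against 2 comparison and 20 with the Actb ratio as a covariate. Leaving out 1 array gave 22 to 97 genes, with fewer arrays. None of the 85 changed sign in those fits, which is fixed in advance for genes with groups that do not overlap. The other settings gave 58 to 122. A sex covariate left the type II median at -1.02, as it must with 1 male and 2 females in each group, so it tests nothing there. The Mia change lay between 4.90 and 5.35 in every setting it was computed for, and the alternative of another Mia probe set was not run, since the array has 1. The 14 lists became 0 with an estimated correlation and 7 with fry, and lay between 10 and 16 in the rest, with 2 of the 10 higher under the Actb ratio covariate. The 175 genes apart at E11.5 became 95 with a pseudocount 4 times as large, 78 with a filter at the 60th percentile and 51 at 3-fold, where fewer genes or a wider fold are part of the setting. The genes that reversed had changes close to 0. Sftpc was -0.0171 with median centring, -0.0125 with quantile normalization, -0.0213 with array weights, -0.0355 in the 2 against 2 comparison and -0.0667 to 0.118 leaving out 1 array. Foxj1 was 0.00743 in the 2 against 2 comparison, 0.172 with the Actb ratio as a covariate and -0.178 to 0.112 leaving out 1 array, Hopx was 0.083 with the Actb ratio, and Mki67 was -0.0856 to 0.00149. The 12 E11.5 lists apart became 8 to 12 over the settings. The cartilage list, called apart towards trachea at -0.514, was 0.0443 with no filter. The cause was not tested for any other change. Both bias sets stayed without a call in every setting. Signals near the 20th percentile of the array limit the folds of genes such as Acoxl and S100g at E18.5 and Mia, Lama3 and Kcne1l at E11.5.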

Other observations

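Of 25 pan-epithelial genes 20 had positive and 5 negative log2 changes, and none passed over all genes. Foxa1, Epcam and Grhl2 had log2 changes of 0.85, 0.63 and 0.41, and Krt19 and Rab25 had -0.48 and -0.30. No set test was run on this list. Lef1, a Wnt effector, had -1.04 and Shh, a signal of distal epithelium, 0.35, and neither passed (limma adjusted p = 0.345 and 0.378). These genes were chosen after their values were seen. Lists with under 5 measured members at E18.5, those of basal cells, neuroendocrine cells, lymphocytes, skeletal muscle and liver or gut neighbours, held no gene past the threshold.

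Both tests on pharyngeal and neural crest genes were set after Six2, Twist1 and Dlx2 had been seen to be higher in the E11.5 trachea array, with a list of other genes written before their values were seen. A hypothesis is that neighbouring pharyngeal arch or neural crest tissue in the trachea sample may account for that pattern. The 11 of 25 listed genes that could be measured had a median log2 lung over trachea ratio of -0.477, at percentile 0.37 of random lists, but its bootstrap 95% interval, -0.663 to 0.207, included 0, and 7 of the 11 were higher in trachea, none by over 2-fold. A larger share of mesenchyme in the trachea sample may do so as well, since the mesenchymal matrix list had a median of -0.466, inside that interval. The most abundant of the 11, Prrx2 (2647 in lung and 3917 in trachea) and Sox10 (939 and 1370), were present in both samples. The explanations were not separated by these 2 arrays.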
